A study of Mus musculus with 4 samples.

How the data were processed

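RNA was measured in 4 samples of sorted retinal neurons from mice at postnatal day 6, 2 of MP amacrine cells and 2 of MP bipolar cells. Per the labels' protocols, carrier males were mated with females lacking the MP transgene, retinas of the mixed-strain offspring were dissociated with papain, amacrine cells were sorted as cells positive for CFP and VC1.1, and bipolar cells were sorted as VC1.1-negative and CFP-positive after VC1.1-positive cells had been taken out on a magnetic column. About 1000 cells gave each replicate. RNA was extracted with the PicoPure kit, amplified in 2 rounds and labelled with biotin with the MessageAmp kit before hybridisation to Affymetrix arrays, per the labels' protocols. Every sample was assigned to its group by its title in the labels. Replicates within a group came from different litters.

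The deposited table holds 1 intensity per probe set and array, on a linear scale, for 45101 probe sets. The software by which the authors summarised, background-corrected and scaled these intensities is not given in the sources used here. No intensity lay at or below 0, and between 3.06% and 3.62% of the probe sets of an array lay at or below 1, nearly all of them at exactly 1, and the lowest value was 0.73. The table carries no detection calls. On the log2 scale the quartiles of the arrays differed by at most 0.0621, so the values were used as deposited, as log2(intensity + 16). Fold changes are therefore on the log2(intensity + 16) scale, which understates the difference of dim genes. Between 27.8% and 28.7% of the probe sets of an array had an intensity below 16.

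The 64 control probe sets were left out of the tests. Of the other 45037, the platform annotation gives exactly 1 gene for 34945, several for 932 and none for 9160, and only the first were given a gene. Gene symbols were looked up by gene identifier in a RefSeq table, which held 18032 of the 18194 genes and changed 0 symbols. Where a gene had several probe sets, the one with the highest mean log2 value stood for it. A gene was tested when that probe set lay above the array's median on at least 2 of the 4 arrays, which held for 11583 genes. The remaining 6611 were too dim. Among the named genes, 73 had other probe sets above the same filter, and for 66 of these every such probe set had the same sign.

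MP amacrine cells were compared with MP bipolar cells by limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05 on the adjusted p. The fit had 2 residual degrees of freedom. Gene lists were tested with limma's camera with a preset correlation of 0.01 between genes, Benjamini-Hochberg adjusted over the 39 lists that had at least 3 tested members. With the correlation estimated from the data, none of the 11 lists called by camera passed, and fry, also of limma, called 13 lists. Where the text says that a count was adjusted over the list alone, the adjustment covered the tested members of that list.

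The 40 gene lists, the tests, the thresholds, the alternatives and the rule for naming genes were fixed before the data were examined. The genes named include Neurod6, the 15 called genes with the largest positive and the 15 with the largest negative log2 fold change. Both sets of 15 were limited to genes whose amacrine arrays both lay on one side of both bipolar arrays. Up to 4 called members of each list by absolute log2 fold change were named too, or the brightest member where none was called. All members on the array were named for the lists of Neurod6-expressing amacrine types and of presynaptic GABA and glycine transmission. The rule took 138 genes, 133 of them tested. Elavl2, Glul, Prkca, Sag, Gngt1, Clu, Nefm, Nefl, Calb1, Eif2s3y and Ctss were chosen for naming after their values were seen. A few list genes without a probe set of their own were not analysed here.

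The alternatives were quantile, cyclic loess and median scaling, no filter and a filter at the 75th percentile, pseudocounts of 1 and 64, other choices among the probe sets of a gene, other variance moderation, other thresholds, all probe sets tested singly, the replicate number as a block, each replicate left out, and the other list tests. A planned offset for tables on a log2 scale was not run, because the table is linear. Array quality weights and the omission of probe sets that can match several transcripts were added after seeing the data. Where leaving out a replicate left a group with 1 array, that array was assumed to vary like the other group.

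The gene and list tests were tested on simulated data, 20 runs with 11583 genes. In each run 200 genes drawn at random were changed between MP amacrine and MP bipolar arrays. The other tested members of the list of markers shared by amacrine types were all raised by 2 on the amacrine arrays. Of the 200, the tests recovered 28.3% of those changed by 1 on the log2 scale, 95.9% of those changed by 2 and 99.4% of those changed by 3. They made 9.15 false calls among 186.75 calls on average and found the shifted list in 20 of 20 runs. The simulated arrays were drawn with equal quality. Fewer genes were changed than the 1559 called in the data, so the shares recovered need not carry over. Genes were drawn independently of each other, with variances from the fitted limma model. The runs therefore cannot show how the list test behaves where genes are correlated or where members of a list move in different directions. Tables were prepared with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and figures drawn with matplotlib 3.10.9.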

Results

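The series profiled retinal neurons of mice at postnatal day 6 that carry the MP transgene, a reporter that marks cells with the fluorescent protein CFP. The VC1.1 antibody, which binds amacrine but not bipolar cells, was used to sort the CFP-positive neurons into MP amacrine cells (CFP-positive and VC1.1-positive) and MP bipolar cells (CFP-positive and VC1.1-negative). Amacrine cells are inhibitory interneurons of the inner retina, and bipolar cells carry photoreceptor signals to it. Each group had 2 biological replicates from different litters, each of about 1000 cells and each measured on 1 Affymetrix array, so 4 arrays were compared. The comparison asks which genes separate MP-expressing amacrine cells from MP-expressing bipolar cells, among them Neurod6, the transcription factor named in the title of the series.

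The median probe set intensity lay between 44.5 and 47.1 on the 4 arrays. Across genes, which are not independent replicates, the Pearson correlation of log2 values was 0.973 between the amacrine arrays, 0.982 between the bipolar arrays, and 0.931 to 0.946 between arrays of different groups. MP amacrine replicate 2 stood apart in its control probe sets. Its Gapdh signal was 3.16 higher on the log2 scale at the 3-prime than at the 5-prime end, against 1.77 to 1.98 on the other arrays, and its actin difference, 3.69, was the largest of the 4 arrays. On that array the mean intensities of the bioB and bioC controls were 1126 and 1857, against 394 to 590 and 792 to 1032 on the others. Those of the creX control were alike, at 7019 to 7198. With 2 arrays per group, their number limits the precision of every value.

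Neurod6, a basic helix-loop-helix (bHLH) transcription factor, was among the genes that differed most. Its intensity was 1586 ± 132 (SD, n = 2) in MP amacrine cells and 7.77 ± 2.52 (SD, n = 2) in MP bipolar cells, a log2 fold change of 6.08 (SE 0.22, adjusted p = 1.25e-05, limma). Ebf3 (6.81, SE 0.22) and Ebf1 (5.93, SE 0.24), transcription factors of the Ebf family, Ret (6.38, SE 0.22), a receptor for GDNF-family ligands, and Lhfp (6.44, SE 0.21) were higher in amacrine cells by a similar amount. Among the genes higher in bipolar cells were Hs3st2 (-6.04, SE 0.30), a heparan sulfate sulfotransferase, and Glra1 (-5.80, SE 0.26), a glycine receptor alpha subunit. The order of such genes depends on the offset of 16, and with an offset of 1 Postn (-7.22) and AW551984 (-7.14) stood above Hs3st2 (-6.66) and Glra1 (-6.62). Of 11583 genes tested, 758 were higher in MP amacrine cells and 801 higher in MP bipolar cells at an adjusted p under 0.05 (limma, n = 2 per group), and 601 and 596 of these differed by at least 2-fold. All 1559 had both amacrine arrays on one side of both bipolar arrays, as did 53.3% of all tested genes, where chance gives 33.3%. Without MP bipolar replicate 2 the number of calls was 917, of which 501 were higher in amacrine cells.

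**Figure D1:**
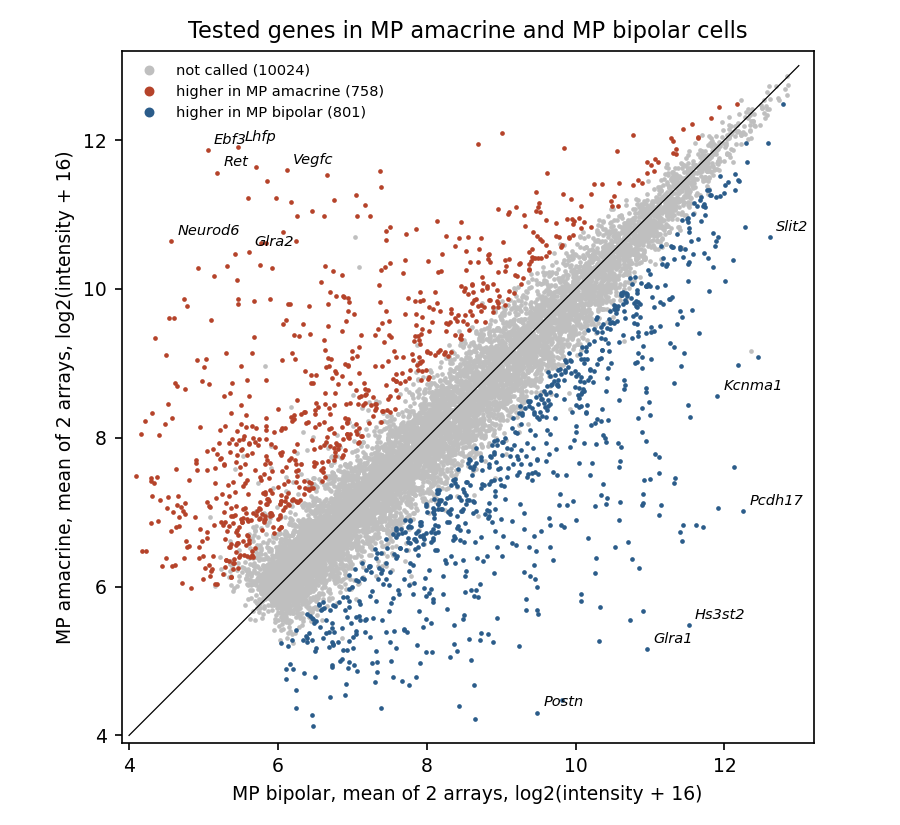
Each point is a tested gene, placed by its mean over the 2 MP bipolar arrays (horizontal axis) and over the 2 MP amacrine arrays (vertical axis), both as log2(intensity + 16), with the diagonal marking equal levels. The 758 genes higher in amacrine cells lie above the diagonal and the 801 higher in bipolar cells below it, with Neurod6 and Ebf3 far to the upper left and Hs3st2, Glra1 and Postn far to the lower right.

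The other genes with the largest positive fold changes were the transcription factor Nhlh2 (5.62), the retinoic acid binding protein Crabp1 (5.60), the growth factor Vegfc (5.48), the proteoglycan Spock1 (5.35), the R-spondin receptor Lgr5 (5.24), Kif26a (5.11), the potassium channel subunit Kcna1 (5.08), the ephrin receptor Ephb1 (5.04), the Rac regulator Chn2 (5.03) and Resp18 (5.01). Their adjusted p lay between 1.29e-05 and 2.71e-05. The other genes with the largest negative fold changes were AW551984 (-5.34), the protocadherin Pcdh17 (-5.24), the organic anion transporter Slco4c1 (-5.24), the matrix protein Postn (-5.18), the transcription factor Fezf2 (-5.18), the adhesion protein Slitrk6 (-5.04), the calcium-binding protein Cabp5 (-4.91), the neurokinin receptor Tacr3 (-4.86), Otor (-4.81), the myosin kinase Mylk (-4.80), the calcium channel subunit Cacna2d1 (-4.67), and the zinc finger factors Zfhx4 (-4.61) and Zfp521 (-4.61). Their adjusted p lay between 1.29e-05 and 0.00238. A 2nd probe set of AW551984 had the opposite sign, at 0.44.

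Genes of the Neurod6-expressing amacrine types were the list with the largest mean difference. These types include an amacrine type known as nGnG, which lacks markers of both GABA and glycine release, and a type known as SEG. Of 9 tested members, 7 were higher in MP amacrine cells and none was higher in bipolar cells (8 and 0 adjusted over the list alone). The mean log2 fold change was 3.52 (camera adjusted p = 5.41e-11, and adjusted p = 0.355 with an estimated correlation). Besides Neurod6, Ebf3 and Ebf1, they were the phosphatase regulator Ppp1r17 (4.59, SE 0.24), Neurod2 (4.48, SE 0.34), the glycine transporter Slc6a9 (2.40, SE 0.26) and Satb1 (0.62, SE 0.15). Satb1 was the exception across probe sets, since its 2nd brightest probe set gave -1.39 and was called in the opposite direction (adjusted p = 0.0272), so its direction was not settled. Ebf2 (0.52, adjusted p = 0.182) and Bcl11b (0.24, adjusted p = 0.578) did not pass the test. Tbr1, Cck, Gbx2 and Lhx9 were too dim to be tested, with group mean intensities from 3.69 to 21.1. Part of this list is known from work on these cells, so its direction here is not independent evidence.

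Markers shared by amacrine types were also higher in MP amacrine cells, 11 of 17 tested, with 1 higher in bipolar cells (13 and 1 adjusted over the list alone). Their mean log2 fold change was 2.26 (camera adjusted p = 5.41e-11, and adjusted p = 0.355 with an estimated correlation). The transcription factors Tfap2c (4.99, SE 0.34) and Pax6 (4.56, SE 0.24) and the noncoding RNA Snhg11 (4.13, SE 0.55) were examples, while the RNA-binding protein Elavl2 (-1.38) was the member higher in bipolar cells. Markers of other amacrine types moved both ways. Of 6 tested AII, dopaminergic, VGluT3 and peptidergic markers, 3 were higher in MP amacrine cells and 1 in bipolar cells, both as tested and adjusted over the list alone (mean 1.23, camera adjusted p = 0.0503, and 0.0290 to 0.0369 with each replicate left out in turn). They were Prox1 (3.26, SE 0.41), the adaptor Dab1 (2.59, SE 0.20) and calretinin, Calb2 (2.45, SE 0.32), against the gap junction gene Gjd2 (-0.95, SE 0.24). Of 10 tested starburst amacrine markers, 2 were higher in amacrine and 5 in bipolar cells (4 and 5 adjusted over the list alone), with a mean of -0.51 and a camera adjusted p of 0.293. With the filter at the 75th percentile the mean was -1.75 (adjusted p = 0.00342). Rnd3 (-3.08), Megf10 (-2.99), Slit2 (-1.92) and Fezf1 (-1.88) were all higher in MP bipolar cells.

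Markers shared by bipolar types were lower in MP amacrine cells, 13 of 18 tested, and none was higher (13 and 1 adjusted over the list alone). Their mean log2 fold change was -2.18 (camera adjusted p = 6.29e-10, and adjusted p = 0.45 with an estimated correlation). After Fezf2 and Cabp5 the largest were the carbonic anhydrase relatives Car10 (-3.88, SE 0.22) and Car8 (-3.58, SE 0.32). The 2nd brightest probe set of Car10 gave 0.27. Cabp5 differed between the amacrine arrays, at 259 and 29.4, against 3251 and 3428 on the bipolar arrays. Of 19 tested markers of single cone bipolar types, 11 were higher in MP bipolar and 2 in MP amacrine cells (12 and 3 adjusted over the list alone). The mean was -1.29 (camera adjusted p = 3.57e-04, and adjusted p = 0.45 with an estimated correlation). Pcdh17, Tacr3 and Zfhx4 led this list, and Ebf1, which some bipolar types express, was its member with the largest change toward amacrine cells. Of 7 tested rod bipolar markers, 2 were higher in MP bipolar cells and none in amacrine cells, both as tested and adjusted over the list alone (camera adjusted p = 0.204). They were Car8 and Rpa1 (-0.94, SE 0.21), while the kinase Prkca had intensities of 484 ± 8.43 and 406 ± 17.1 (SD, n = 2) in amacrine and bipolar cells.

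**Figure D2:**
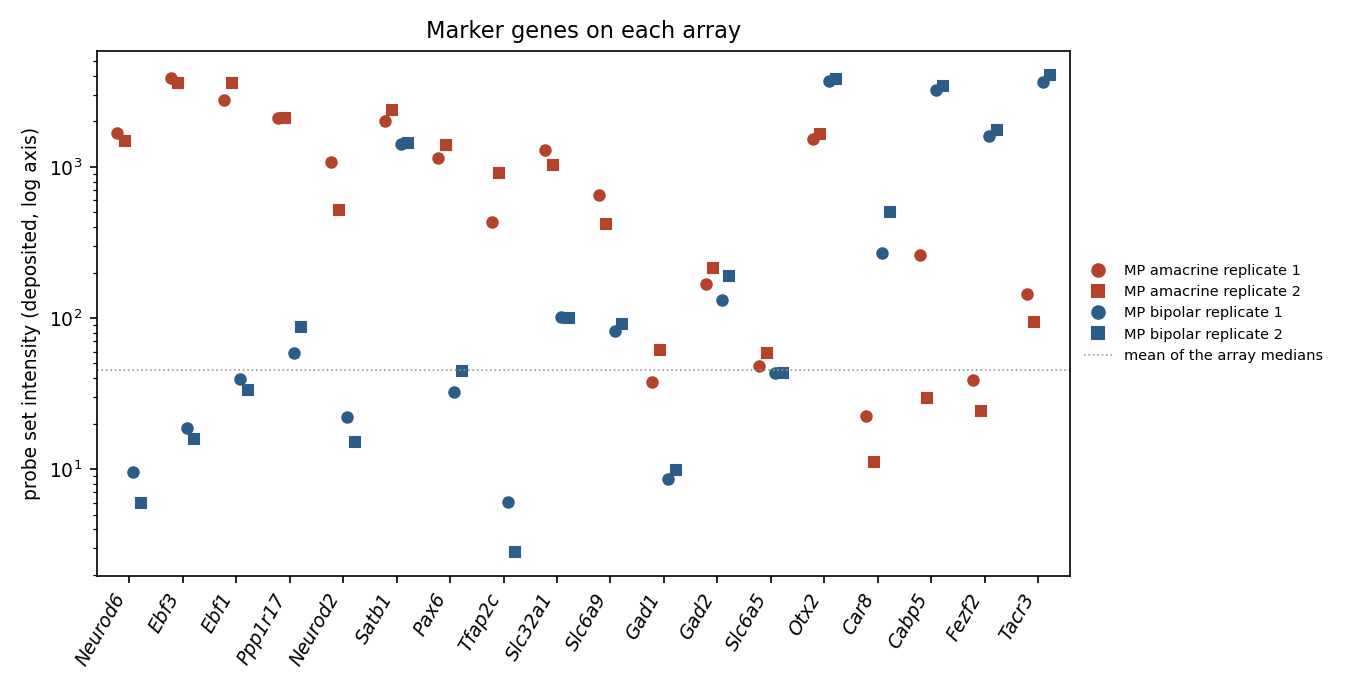
Deposited intensity on a log axis of single genes on the 2 MP amacrine arrays (red) and the 2 MP bipolar arrays (blue), 1 symbol per array, with the dotted line at the mean of the array medians. Neurod6 lies at 1680 and 1493 on the amacrine arrays and at 9.55 and 5.99 on the bipolar arrays, while Gad2 and Slc6a5 overlap or lie close between the groups.

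Among presynaptic genes of GABA and glycine transmission, the vesicular transporter Slc32a1 was 3.33 higher (SE 0.23, adjusted p = 7.06e-05, limma) in MP amacrine cells on the log2 scale. Slc6a9 and the GABA-degrading enzyme Abat (1.81, SE 0.27) were the other members called of 7 tested, and none was higher in bipolar cells (3 and 2 adjusted over the list alone). The list did not pass its own test (mean 0.96, camera adjusted p = 0.0591), although it did without MP amacrine replicate 1 (adjusted p = 0.042), without MP bipolar replicate 2 (adjusted p = 0.0325), and with the filter at the 75th percentile (adjusted p = 0.00955). The GABA-synthesising enzyme Gad2 (0.25, adjusted p = 0.635) and the neuronal glycine transporter Slc6a5 (0.22, adjusted p = 0.588) did not differ detectably. Gad1 was too dim to be tested, with 49.8 ± 16.8 in amacrine and 9.26 ± 0.955 (SD, n = 2) in bipolar cells. Slc6a11 (-0.67, adjusted p = 0.0631) and Aldh5a1 (-0.59, adjusted p = 0.123) did not pass. For Abat the 2nd brightest probe set, which lay below the filter, gave -0.11. Of 6 tested presynaptic genes of glutamate transmission, 1 was higher in each group, also adjusted over the list alone (camera adjusted p = 0.779). These were the glutamate transporters Slc1a3 (1.65, SE 0.38) in amacrine and Slc1a2 (-2.71, SE 0.26) in bipolar cells.

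Components of the ribbon synapse, the release site of bipolar cells and photoreceptors, were higher in MP bipolar cells for 5 of 14 tested genes and higher in amacrine cells for 1 (6 and 1 adjusted over the list alone). The mean was -0.75 (camera adjusted p = 0.0114, and adjusted p = 0.45 with an estimated correlation). The calcium channel genes Cacna2d4 (-3.36, SE 0.27) and Cacna1f (-3.09, SE 0.24) and the release factor Unc13b (-2.32, SE 0.18) led, and another calcium channel gene, Cacna1d (1.68, SE 0.24), went the other way. Of 2 other Cacna2d4 probe sets above the filter, 1 had the opposite sign. Of 21 tested components of conventional synapses, 3 were higher in amacrine and 2 in bipolar cells (4 and 3 adjusted over the list alone, camera adjusted p = 0.779), with Rab3c (2.11) and Cacna1b (1.10) against Nsf (-1.41) and Sv2b (-0.97). The cascade of the glutamate receptor mGluR6, by which ON bipolar cells respond to light, had 4 of 7 tested members higher in MP bipolar cells and none higher in amacrine cells, both as tested and adjusted over the list alone (mean -1.25, camera adjusted p = 0.0168, and adjusted p = 0.45 with an estimated correlation). Without the filter on dim probe sets it did not pass (adjusted p = 0.0574). The G protein regulators Rgs7 (-3.18, SE 0.22), Rgs11 (-2.55, SE 0.20) and Rgs7bp (-1.24, SE 0.30) and the G protein subunit Gnb3 (-2.27, SE 0.29) were the called members. Grm6, the gene of the receptor itself, and Trpm1 were not among the called members. Of 10 members on the array 7 were tested, and 3 of these were not called.

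Receptors and channels were split by subunit. Among 15 tested GABA and glycine receptor genes, 7 were higher in MP bipolar and 3 in MP amacrine cells (9 and 3 adjusted over the list alone). The mean was -0.99 (camera adjusted p = 0.0409, and adjusted p = 0.608 with an estimated correlation). Glra1 and the GABA receptor subunits Gabrb1 (-4.01, SE 0.26) and Gabrr1 (-3.78, SE 0.52) were higher in bipolar cells, and the glycine receptor subunit Glra2 (4.89, SE 0.24) was higher in amacrine cells. This list no longer passed without MP amacrine replicate 2 (adjusted p = 0.0628) or after median scaling (adjusted p = 0.0537). Of 11 tested ionotropic glutamate receptor genes, 4 were higher in amacrine and 3 in bipolar cells (5 and 4 adjusted over the list alone, mean 0.37, camera adjusted p = 0.257, and mean 1.14 with adjusted p = 0.00948 with the filter at the 75th percentile). Examples were Grik2 (4.22, SE 0.23) and Gria3 (1.82, SE 0.27) against Grik1 (-2.27, SE 0.25) and Gria1 (-1.78, SE 0.40). Of 7 tested nicotinic and muscarinic receptor genes, 1 was higher in amacrine and 2 in bipolar cells (2 and 3 adjusted over the list alone, camera adjusted p = 0.583). They were Chrna5 (1.69) against Chrna7 (-1.65) and Chrna4 (-2.56). The 2 other Chrna4 probe sets above the filter had the opposite sign, the brighter of them at 0.31. Voltage-gated sodium and potassium channel genes had 7 of 21 tested members higher in MP amacrine and 2 higher in bipolar cells (9 and 3 adjusted over the list alone). The mean was 0.70 (camera adjusted p = 0.0108, and adjusted p = 0.45 with an estimated correlation). Kcna1, Scn2a (3.13, SE 0.42) and Scn3b (2.65, SE 0.24) were examples, and the calcium-activated channel gene Kcnma1 (-3.35, SE 0.17) was higher in bipolar cells.

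Cell adhesion and guidance genes differed member by member. Among 31 tested cadherins and protocadherins, 14 were higher in MP bipolar and 6 in MP amacrine cells (15 and 6 adjusted over the list alone), with a camera adjusted p of 0.0518 (0.0157 without MP amacrine replicate 2, 0.0182 without MP bipolar replicate 2, 0.0378 after quantile and 0.0340 after loess scaling, and 0.0171 with the filter at the 75th percentile). Pcdh17, Clstn2 (-4.40, SE 0.22) and Pcdh10 (-3.80, SE 0.24) stood against Pcdh8 (3.92, SE 0.25). Leucine-rich repeat proteins had 11 of 29 tested members higher in bipolar and 4 higher in amacrine cells (11 and 6 adjusted over the list alone), also with a camera adjusted p of 0.0518 (0.0205 to 0.0481 with each replicate left out in turn, 0.0300 after quantile and 0.0298 after loess scaling). With the filter at the 75th percentile the mean of these proteins moved from -0.68 to -1.32 (adjusted p = 0.00190). Slitrk6, the guidance ligand Slit1 (-4.27, SE 0.59) and Lrit2 (-3.51, SE 0.50) contrasted with Lrfn5 (3.93, SE 0.26). Of 35 tested immunoglobulin superfamily genes, 13 were higher in bipolar and 5 in amacrine cells (14 and 7 adjusted over the list alone, camera adjusted p = 0.0897, and 0.0255 without MP amacrine replicate 2), such as Cntn1 (-3.26), Ntm (-2.82) and Igsf3 (-2.51) against Kirrel3 (2.64). Of 38 tested semaphorin, plexin, ephrin and Eph receptor genes, 7 were higher in amacrine and 6 in bipolar cells (8 and 7 adjusted over the list alone, camera adjusted p = 0.198), with Ephb1 and its class of ligand Efnb2 (3.73, SE 0.23) against Epha3 (-4.17, SE 0.26) and Epha5 (-3.29, SE 0.21).

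The HNK-1 carbohydrate is the sugar epitope of the VC1.1 antibody. B3gat1, the glucuronyltransferase that makes it in neurons, was 1.95 higher (SE 0.15, adjusted p = 1.31e-04, limma) in MP amacrine cells with intensities of 3011 and 2989 on the amacrine arrays and 730 and 804 on the bipolar arrays. Of 13 tested genes for its synthesis and carriers, 3 were higher in each group (4 in each adjusted over the list alone, camera adjusted p = 0.656), with Ncan (1.63) and L1cam (1.59) against Cntn1. For L1cam the 2nd brightest probe set, which lay below the filter, gave -0.34.

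Among transcription factors, 8 of 18 tested bHLH and related genes were higher in MP amacrine cells and none was higher in bipolar cells (8 and 1 adjusted over the list alone). The mean of the list was 1.46 (camera adjusted p = 6.49e-05, and adjusted p = 0.45 with an estimated correlation). Neurod6, Nhlh2, Neurod2 and the Notch effector Hes5 (3.19, SE 0.31) were the largest. Of 31 tested homeodomain and related factors, 8 were higher in each group (11 in amacrine and 9 in bipolar cells adjusted over the list alone, camera adjusted p = 0.322), with Pax6, Meis2 (3.32, SE 0.28) and Prox1 against Zfhx4.

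**Figure D3:**
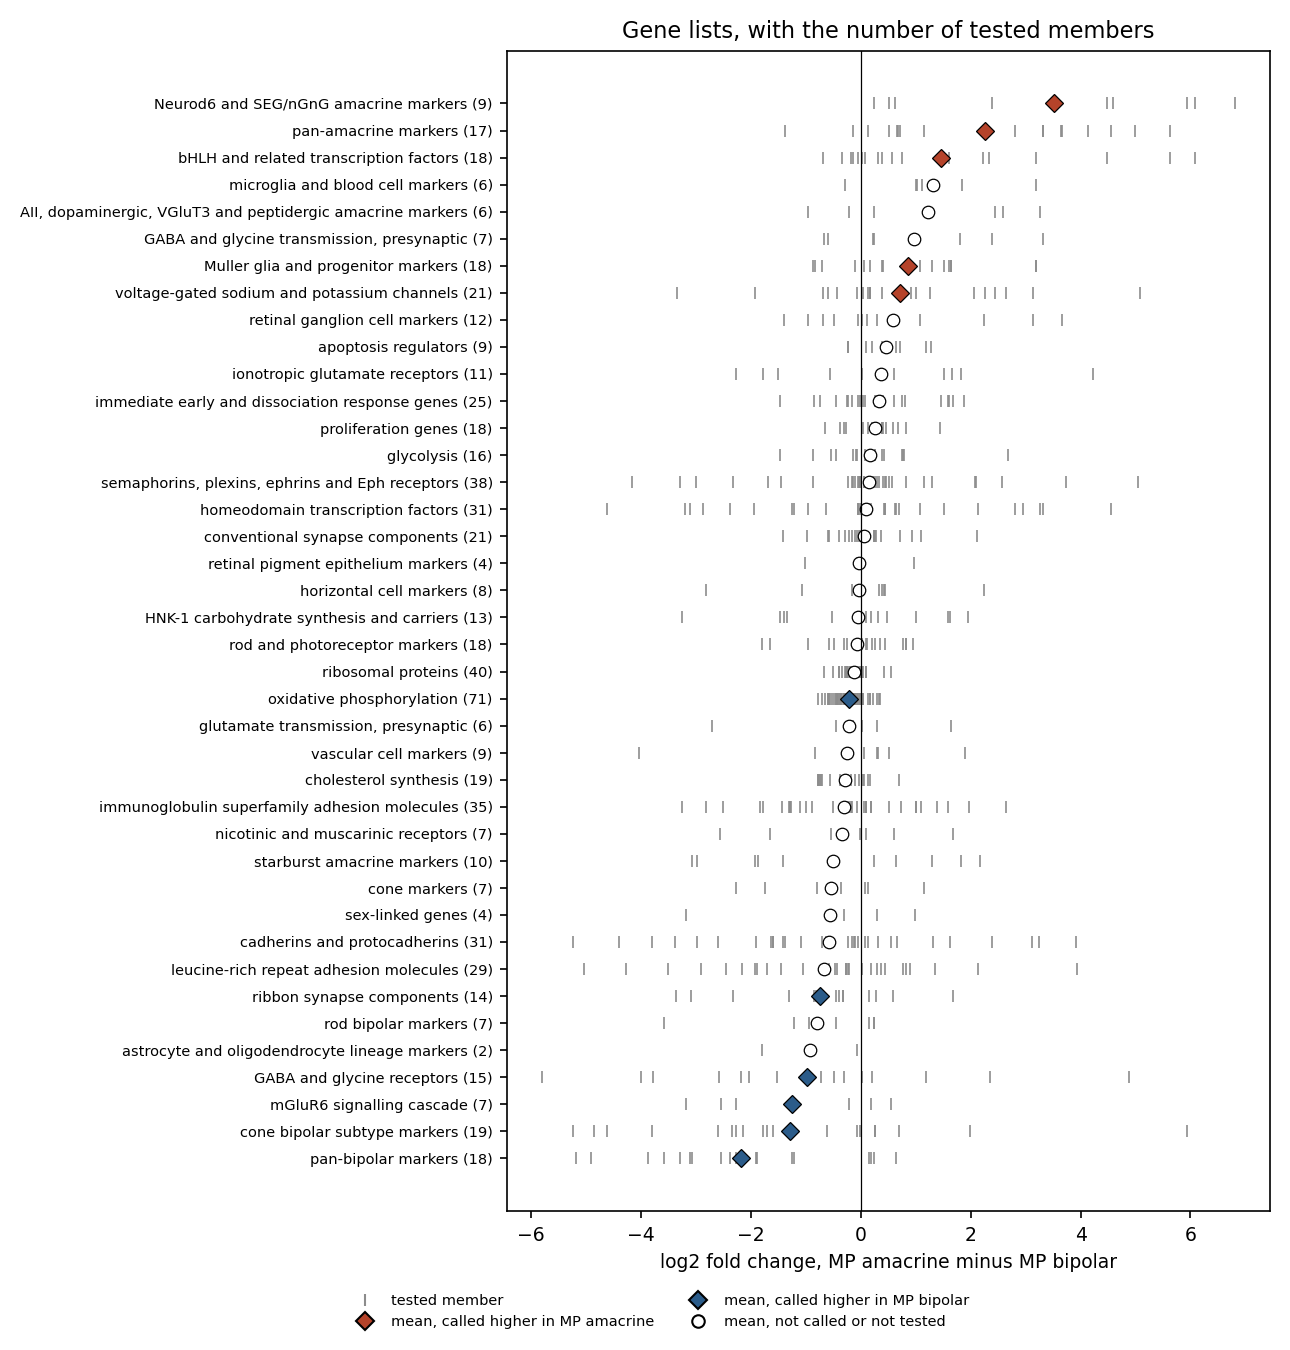
Log2 fold change (MP amacrine minus MP bipolar) of the tested members of each gene list (grey ticks) and their mean, as a filled diamond where the list passed camera at an adjusted p under 0.05 and as an open circle otherwise, with the number of tested members in brackets. The Neurod6 and SEG/nGnG list has the highest mean, 3.52, and the pan-bipolar list the lowest, -2.18, while lists such as the cadherins span both directions.

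Markers of other cell types that the sorts could hold were measured in the same way. Müller glia and progenitor markers had 6 of 18 tested members higher in MP amacrine and 1 in MP bipolar cells (10 and 2 adjusted over the list alone). The mean of the list was 0.86 (camera adjusted p = 0.00122, and adjusted p = 0.45 with an estimated correlation). Vim (3.19, SE 0.33), Hes5, Slc1a3 and Dkk3 (1.60, SE 0.21) were the largest, while glutamine synthetase, Glul, was at 1987 ± 165 and 1766 ± 242 (SD, n = 2). Proliferation genes had 2 of 18 tested members higher in amacrine and none higher in bipolar cells, both as tested and adjusted over the list alone. Their mean was 0.26 (camera adjusted p = 0.0827, and 0.0290 without the filter on dim probe sets), and 0.35 without MP amacrine replicate 1. The called members were Mcm7 (1.44) and Nusap1 (0.83). The 2nd brightest probe set of Nusap1, which lay below the filter, gave -0.28. The rod phototransduction genes Sag and Gngt1 had intensities between 1983 and 4138 on all 4 arrays. Of 18 tested rod and photoreceptor markers, 2 were higher in each group, also adjusted over the list alone (camera adjusted p = 0.656), namely Prdm1 (0.95) and Rp1 (0.82) against Unc119 (-1.80) and Crx (-0.97). Of 7 tested cone markers, 1 was higher in each group (1 in amacrine and 2 in bipolar cells adjusted over the list alone, camera adjusted p = 0.443), Gnat2 (1.15) and Gnb3.

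Of 12 tested ganglion cell markers, 1 was higher in amacrine and 2 in bipolar cells (3 in each adjusted over the list alone, camera adjusted p = 0.583), Stmn2 (3.67, SE 0.36) against Thy1 (-1.41, SE 0.28) and Jam2 (-0.97), of which 2 of 3 other probe sets had the opposite sign. Of 8 tested horizontal cell markers, Vat1l (-2.82) alone was called, also adjusted over the list alone (camera adjusted p = 0.756). Of 9 tested vascular markers, Pdgfrb (1.89) was higher in amacrine cells, and Esam (-4.04) and Ramp2 (-0.83) in bipolar cells. The counts were the same adjusted over the list alone (camera adjusted p = 0.94). The 2nd brightest probe set of Pdgfrb, which lay below the filter, gave -0.04. Of 6 tested microglia and blood markers, Csf1r (1.11, adjusted p = 0.0484, and not called in 10 alternatives) was higher in amacrine cells (2 adjusted over the list alone, camera adjusted p = 0.0548, and 0.00388 without MP amacrine replicate 1 and 7.82e-04 without MP bipolar replicate 1). The list's mean log2 level was 8.63 on MP amacrine replicate 2 against 5.85 to 7.47 on the other arrays. Of 4 tested pigment epithelium markers, Dct (0.97) was higher in amacrine cells (1 in each group adjusted over the list alone, camera adjusted p = 0.797). Of the 2 tested astrocyte and oligodendrocyte markers, too few for camera, Mbp (-1.80) was higher in bipolar cells, also adjusted over the list alone, although the 1 of its 7 other probe sets above the filter gave 0.25. None of 4 sex-linked genes was called (1 in each direction adjusted over the list alone, camera adjusted p = 0.796), although Xist (-3.19, adjusted p = 0.112) was called as higher in bipolar cells in 5 alternatives.

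Genes of oxidative phosphorylation had a mean log2 fold change of -0.21 over 71 tested members (camera adjusted p = 0.0237, and adjusted p = 0.826 with an estimated correlation), with no single member called, also adjusted over the list alone. The list's mean log2 level was 9.91 on MP amacrine replicate 2 and between 10.33 and 10.37 on the other arrays, and without that array the mean fold change was 0.02 (adjusted p = 0.708). The list did not pass either without MP bipolar replicate 2 (adjusted p = 0.0778), or after quantile (adjusted p = 0.0745) or loess scaling (adjusted p = 0.0757). Its brightest member, Uqcrb, was at -0.19 (adjusted p = 0.291). Of 40 tested ribosomal protein genes none was called, also adjusted over the list alone, with a mean of -0.12 (camera adjusted p = 0.218, and 2.47e-04 without MP amacrine replicate 1). Without MP amacrine replicate 2, on which their mean log2 level was 10.91 against 11.14 to 11.22 on the other arrays, the mean fold change was 0.03. The brightest, Rps28, was at -0.11 (adjusted p = 0.555).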

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

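Both results below come from probe sets that the comparison of genes does not use, and both were looked for after the data were seen. Among 4480 probe sets above the filter that the annotation gives no gene or several genes, 359 differed between MP amacrine and MP bipolar cells when all 23648 non-control probe sets above the filter were tested singly (limma, adjusted p under 0.05, n = 2 per group), 139 of them higher in amacrine and 220 higher in bipolar cells. Over all 23648, 2237 were called, a higher share than among the 4480. A control probe set for the bacterial transcript dap had an intensity of 321.93 on MP amacrine replicate 2 and of 1.73 to 3.30 on the other 3 arrays. No explanation was tested for either.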

How the results depend on the processing

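Array quality weights and the omission of probe sets that match several transcripts were added after seeing the data. The weights were 0.78 for each amacrine and 1.28 for each bipolar array, so they could not set MP amacrine replicate 2 apart from replicate 1. The number of called genes, 1559, stayed within 1.5 times under quantile, loess and median scaling (1378 to 1497), the stricter filter (1304) and both pseudocounts (1498 and 1576). Under quantile and loess scaling none of the 1559 changed sign. Without a filter on dim probe sets 785 genes were called (400 higher in amacrine, 385 in bipolar cells), at an adjusted p under 0.01 883 (444 and 439), at an unadjusted p under 0.05 2857 (1284 and 1573), and with the 2nd brightest probe set of each gene 562 (280 and 282). In the last choice genes with only 1 probe set kept it, so these could not turn. The choice turned the sign of 209 of the 1559, but it also took probe sets that lay below the filter. Leaving out each replicate gave 917 to 1939 calls (501 to 763 higher in amacrine, 416 to 1176 in bipolar cells) and 13 to 19 called lists, with 917 without MP bipolar replicate 2 and 19 lists without MP amacrine replicate 1, and the cause was not tested. Nothing ties the replicate numbers of the groups to a shared litter, and same-numbered arrays deviated together with r = -0.0813 over 23648 probe sets, so they share only a number. With the replicate number as a block, 1932 genes and 16 lists were called.

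The mean shifts of the pan-amacrine and pan-bipolar lists stayed past the threshold in all settings but the estimated correlation, which left 2.26 at an adjusted p of 0.355 (6.54e-15 to 0.355 over the alternatives) and -2.18 at 0.45 (6.54e-15 to 0.45) and called 0 of the lists. That correlation rests on 2 residual degrees of freedom. By fry, which called 13 lists, the GABA and glycine receptor, Müller glia and oxidative phosphorylation lists did not pass (adjusted p = 0.124, 0.0568 and 0.524), while the starburst list, among 5 added, did (adjusted p = 0.0185). Without the filter the mGluR6 list, at -0.87, and the GABA and glycine receptor list, at -0.74, did not pass (adjusted p = 0.0574 and 0.107). The oxidative phosphorylation shift, -0.21, was 0.0203 without MP amacrine replicate 2 and -0.44 without replicate 1. It did not pass after quantile or loess scaling or the stricter filter (adjusted p = 0.0745, 0.0757 and 0.0720). The planned offset for a log2 table was not run, as the table is linear.

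Of 124 called named genes, 116 stayed called under all 3 scalings, 122 at both pseudocounts, 98 without each replicate and 57 in every setting that tested them. Without the filter 34 named genes were no longer called, and with the 2nd brightest probe set 51 were not, besides those that turned. Fos lost its call in 13 settings, Csf1r in 10, Cacna1b, Jam2, Pkm and Rp1 in 8, Gjd2, Satb1 and Slc2a1 in 7, Bcl2, Ccn2, Ramp2 and Rgs7bp in 6, and Crx, Gadd45g, Nusap1, Prdm1 and Rpa1 in 5. With the 2nd brightest probe set the sign turned for AW551984 (0.44), Car10 (0.27), Chrna4 (0.31), Mbp (0.25) and Satb1 (-1.39). For Mbp it also turned without probe sets that match several transcripts (0.25). The sign turned as well for Abat (-0.11), L1cam (-0.34), Nusap1 (-0.28) and Pdgfrb (-0.0408), whose other probe sets all lay below the filter. The cause of these turns was not tested.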

Other observations

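The tests of explanations below were all chosen after the results were seen. Among gene groups not described so far, glycolysis split by enzyme. Of 16 tested genes 5 were higher in MP amacrine and 2 in MP bipolar cells (6 and 2 adjusted over the list alone, camera adjusted p = 0.243). The hexokinase Hk2 (2.69, SE 0.26) and the glucose transporter Slc2a1 (0.79, SE 0.18) were higher in amacrine cells, and the neuronal enolase Eno2 (-1.48, SE 0.26) and pyruvate kinase, Pkm (-0.87, SE 0.21), in bipolar cells. Of 19 tested genes of cholesterol synthesis, the regulator Insig1 (-0.75, SE 0.16) alone was called, also adjusted over the list alone (camera adjusted p = 0.136). Of 9 tested apoptosis regulators, Bcl2 (1.29, SE 0.33), which restrains cell death, was higher in amacrine cells (4 adjusted over the list alone, camera adjusted p = 0.0709, and 0.042 without MP amacrine replicate 1). Of 25 tested immediate early and dissociation response genes, 5 were higher in amacrine and 2 in bipolar cells (6 and 3 adjusted over the list alone, camera adjusted p = 0.183, and 0.0358 and 0.0411 without replicate 1 of amacrine or bipolar cells), such as Ier2 (1.87), Ccn2 (1.68), Fos (1.60) and Gadd45g (1.59). Fos was not called in 13 alternatives, all 3 scalings among them, Ccn2 in 6 and Gadd45g in 5.

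Some genes differed between replicates of a group. Nefm had intensities of 1631 and 136 on MP amacrine replicates 1 and 2, and 47.7 and 35.0 on the bipolar arrays. For Nefl the values were 1102 and 87.5 against 68.6 and 45.7 and for Calb1 517 and 39.5 against 19.2 and 17.0. Nefm and Nefl are ganglion cell markers, and Nefl and Calb1 horizontal cell markers. The mean log2 level of the ganglion cell list was 7.86 on MP amacrine replicate 1 and 6.85 to 7.13 on the other arrays, and that of the horizontal cell list 8.26 against 7.39 to 7.94. Whether this sort held such cells was not tested. Levels of the bipolar lists differed between MP amacrine replicates 1 and 2 as well. Their mean log2 levels were 7.52 and 6.99 for markers shared by bipolar types and 8.23 and 7.74 for rod bipolar markers. Cone bipolar markers went the other way, at 7.06 and 7.21. Xist, expressed from the inactive X chromosome of females, was at 111 and 2574 against 4920 and 5536 (adjusted p = 0.112, limma, and called as lower in amacrine cells in 5 alternatives, among them without either amacrine replicate), while the Y-linked Eif2s3y was at 1806 and 1639 against 1420 and 1386. Ctss, a protease of microglia, was at 567 and 2665 against 1003 and 2.27.

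The lower level of oxidative phosphorylation genes in MP amacrine cells was carried by 1 array. Without MP amacrine replicate 2, the array with the largest 3-prime to 5-prime differences, the mean log2 fold change of the list was 0.0203 in place of -0.21, which locates the shift but not its cause. On that array 85.9% of the 71 tested members lay below both bipolar arrays, and on MP amacrine replicate 1 35.2%, where chance gives 33.3%. From replicate 1 to replicate 2 the list fell by 0.46 (SE 0.04 over genes) on the log2 scale. For 1207 other genes of the same level on the bipolar arrays the mean fall was 0.12 (SE 0.01 over genes), or 25.6% of the list's fall. That mean counts a gene each time it was matched to a list member, and its SE counts each gene once. Genes on 1 pair of arrays are not independent replicates, so these SE do not measure the spread between arrays. RNA or amplification quality of replicate 2 stays open, since it need not act on all genes alike. A lower level in amacrine cells of which replicate 1 is an exception stays open too, since 1 array cannot decide it.

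The higher level of Müller glia and progenitor markers in MP amacrine cells has several candidate explanations. A lower purity of the amacrine sort that raises every other cell type alike stays open. The mean log2 fold change of the list was 1.08 above that of 40 tested rod, cone, vascular, astrocyte and pigment epithelium markers (SE 0.33). That set leaves out the microglia, ganglion cell, horizontal cell and proliferation lists. Over 83 markers of all these types the difference was 0.76 (SE 0.31), and over 58 without rods and cones 0.63 (SE 0.33). The SE of these differences are taken over genes, which are not independent replicates. Rod transcripts were bright on all arrays, so a small share of rods would not show. Müller glia or progenitor cells in the sort, which required both CFP and VC1.1, stay open as well. Of the 26 members on the array, 19, or 73.1%, had a positive fold change, neither nearly all nor an even split. Only 18 of the 26 passed the filter, and the signs of the dimmer members can be noise, so this share cannot decide. Clu, a transcript of Müller glia, was at 158 ± 42.5 in amacrine against 292 ± 44.0 (SD, n = 2) in bipolar cells. Expression of these genes by the amacrine cells themselves was not tested, and 6 of the 26 members also stand in another list.

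The 4 arrays allow 3 splits into 2 and 2, too few for a share under 0.05. The real split called 1559 genes and was the 1 split with that many, and the highest of the others called 0 (limma, with 2857 genes at an unadjusted p under 0.05 in the real split). Each other split puts 1 amacrine and 1 bipolar array in each group. There the difference between the cell types counts as spread within groups, so few calls could arise. The contrast with these splits therefore cannot decide whether chance plays a part.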
